A study of Mus musculus with 30 samples.

How the data were processed

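RNA from the nucleus accumbens of C57BL/6J mice was measured on Illumina bead arrays 4 h after an injection of saline or of dexamethasone, an agonist of the glucocorticoid receptor, at 4 mg/kg. Per the labels, the RNA came from nucleus accumbens tissue, from astrocytes or from neurons, the cells having been sorted magnetically, and each array held RNA of an individual mouse. The 3 preparations and 2 agents made 6 groups of 5 arrays, 30 arrays in all. Per the labels' protocols, RNA was purified on RNeasy columns, and cRNA carrying biotin was made from total RNA with an Illumina amplification kit. The label descriptions placed the 6 arrays of each replicate number on 1 chip and every group at 1 fixed position of the chip, so that position and group cannot be told apart. The scanner software, the background step and the authors' statistical test are not given in the sources used here.

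The authors deposited a table of 46174 probes with log2 intensities that were not normalized between arrays and carried no detection p. They also deposited a value table whose scale and normalization no source states. Its values equalled the log2 of the quantile-normalized log2 intensities, with a largest difference of 5e-10 and a tolerance of 1e-09, and the median was 2.99 in each of the 30 columns. Folds taken from that table are therefore on a compressed scale, and it served as an alternative only. The first table was the starting point of every value below.

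The planned background correction needed detection p, which the files do not give. In its place, 1551 probes for olfactory, vomeronasal, trace amine and taste receptors stood in for negative controls. The intensities were corrected with limma's normexp model on those probes, with an offset of 16, then quantile-normalized over the 30 arrays and taken to log2. The detection p of a probe on an array was the share of receptor probes at or above its intensity. The receptor probes were then removed, which left 44623 probes, and 22519 of them had a detection p under 0.05 on at least 5 arrays.

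Of the 46174 probes, 35725 had 1 gene symbol in the platform annotation, 0 had several and 10449 had none. Symbols were updated through the RefSeq gene table of GRCm38.p6. By Entrez ID 28566 probes matched, by accession a further 2632, and 4527 kept the annotation's symbol; the match changed 936 symbols. The detected probes comprised 19356 with a gene symbol and 3163 without. Each gene was represented by its probe with the highest mean level, which gave 13209 genes tested. For 7 of them the probe lay within 0.5 of the highest intensity, log2 16.11, on all 30 arrays, so that changes there are compressed. Of 106 further detected probes of the genes called in astrocytes, 99 had the same sign as the probe used, 7 had the opposite sign, and 0 of those 7 were called.

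All tests were two-sided and made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjustment over the genes, called at an adjusted p under 0.05). Dexamethasone was compared with saline within each preparation on its 10 arrays. The difference between the responses of 2 preparations was tested as an interaction on all 30 arrays. The preparations were compared with one another on the 15 saline arrays. Log2 differences are given with the standard error of the fit and levels as mean ± SD. A gene not detected on any array of a group has only a bound there, "at least N-fold", taken from the brighter group's mean against, per array of the dimmer group, the higher of the lowest detected level and the gene's own level.

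A set of 25 gene lists, holding 450 genes, and the rule for naming genes were fixed before the data were examined, as were the comparisons, their tests and all alternatives not described below as added. Of the 450 genes, 418 had a named probe and 367 were tested. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. The same test with an estimated correlation stands beside every list call that it ends; each list's mean level per array was also compared with exact permutation tests. The named genes of a treatment comparison were the 12 rising and the 12 falling with the largest change among those called with the same sign on all 5 chips. To these came members of the glucocorticoid list and up to 4 members, by smallest p, of each other list described. Where no gene was called, the 5 with the smallest p were named. For the other comparisons, the 10 genes with the largest difference in each direction were taken, with members of the marker lists. Any other gene is said to have been chosen after its values were seen.

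Replicate numbers pair the arrays through the chip, as the label descriptions state. After subtraction of the group means, arrays of the same preparation on 1 chip correlated with a mean r of 0.19 in astrocytes (lowest -0.04), 0.17 in neurons (lowest 0.07) and 0.05 in tissue (lowest -0.12), against means of -0.05, -0.04 and -0.01 for arrays on different chips. The planned fit had no chip term; the fit with the chip as a block is given where it changes a call.

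The fits were tested on simulated data, with 50 genes planted at each size among 13209. Means and SDs of the genes came from the real arrays, but the noise was normal and independent between genes and arrays. The rates therefore leave out chip effects, correlation between genes and outlying arrays. Changes of log2 2 were recovered in 94% of cases in astrocytes, 96% in neurons and 94% in tissue, and changes of log2 1 in 42%, 64% and 48%. For the response differences, log2 2 was recovered in 70% of cases between astrocytes and neurons, 86% between astrocytes and tissue and 80% between neurons and tissue. For the comparisons of preparations it was 98%, 100% and 98% in that order. Each simulation gave 2 to 15 false calls. The alternatives covered the background correction, the scaling, the filter on dim probes, the choice of probe, the chip as a block, array weights, the variance model, the arrays in the fit, the deposited value table, other thresholds and leaving out each array in turn. The probes of both receptors that dexamethasone and corticosterone bind were detected on too few arrays to enter the tests. Probes without a gene symbol entered no list.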

Results

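Gene expression was compared between saline and dexamethasone in mouse nucleus accumbens tissue and in astrocytes and neurons sorted magnetically, with 5 arrays per group. The series title names changes that depend on the glucocorticoid receptor and are specific to a cell type, and the comparisons below address that question. The percentage of probes detected was 39.7 ± 1.84 (SD, n = 5 arrays) in astrocytes under saline and 39.5 ± 2.63 under dexamethasone. In neurons it was 40.1 ± 1.90 and 39.0 ± 1.10, and in tissue 42.9 ± 1.19 and 41.4 ± 5.23. Correlations between arrays of a group lay between 0.899, in tissue after dexamethasone, and 0.985, in tissue after saline. Over the 30 arrays, principal component 1 held 60.6% of the variance and component 2 held 11.1%.

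Under saline, the astrocyte preparation carried astrocyte transcripts far above the other preparations. The neuron preparation carried those of medium spiny neurons, the main projection neurons of the nucleus accumbens, far above astrocytes. Against tissue the median log2 difference of medium spiny neuron markers was 0.94. The general neuron list did not stand above tissue, with a mean level of 12.12 ± 0.08 in neurons and 12.14 ± 0.09 in tissue (SD, n = 5 saline arrays each). Compared with neurons, astrocytes had higher Slc1a2, a glutamate transporter (log2 difference 5.61 ± 0.37 SE, n = 5 arrays per preparation), Agt, the angiotensin precursor (5.84 ± 0.29), and Entpd2, an ectonucleotidase (5.82 ± 0.30). Lgi4 and Fgfr3, a growth factor receptor of astrocytes, were not detected in neurons and were at least 33.8-fold and at least 29.4-fold higher in astrocytes. Neurons had higher Penk (-5.20 ± 0.36, astrocytes minus neurons), Tac1 (-5.12 ± 0.50) and Drd1, a dopamine receptor (-4.96 ± 0.43), the neuropeptide and receptor genes of medium spiny neurons. Between these preparations 7691 of 13209 genes differed in limma, 3562 higher and 4129 lower in astrocytes.

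All 21 measured astrocyte markers were higher in astrocytes than in neurons, 21 also when adjusted over the list alone (median log2 difference 4.68, camera adjusted p = 2.63e-14). With an estimated correlation the adjusted p = 0.0667. All 15 medium spiny neuron markers were lower, 15 also when adjusted over the list alone (median -3.93, adjusted p = 3.41e-09, and adjusted p = 0.124 with an estimated correlation). Of the 16 neuron markers 12 were lower and 0 higher, 14 lower when adjusted over the list alone (median -2.44, adjusted p = 4.41e-07, and adjusted p = 0.0667 with an estimated correlation). Transcripts of other cells separated the preparations too. Microglia markers were higher in astrocytes than in neurons for 15 of 16 genes and lower for 1, with the same counts when adjusted over the list alone (median 2.78, adjusted p = 2.25e-07, and adjusted p = 0.0667 with an estimated correlation). Mural cell markers were higher for 7 of 10, 7 also adjusted over the list alone, among them Acta2 of smooth muscle (5.21 ± 0.44) and Pdgfrb, which was not detected in neurons and was at least 10.6-fold higher. Their median was 2.92 (adjusted p = 7.7e-04, and adjusted p = 0.161 with an estimated correlation). Glutamate, GABA and potassium handling genes were higher in astrocytes for 15 of 17 and lower for 1, with the same counts when adjusted over the list alone (median 3.71, adjusted p = 1.53e-08, and adjusted p = 0.0667 with an estimated correlation).

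**Figure D1:**
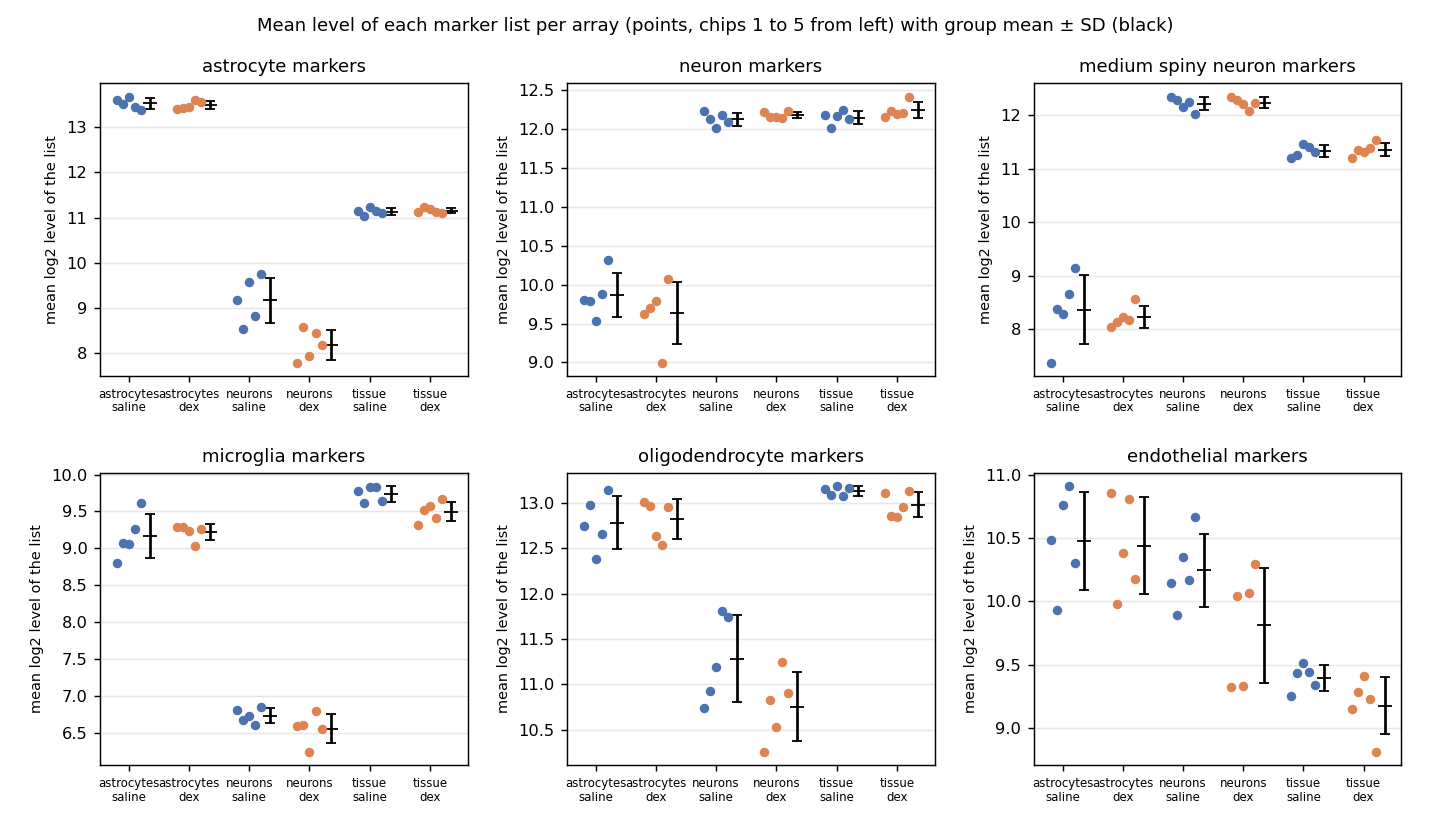
Mean normalised log2 level of 6 marker lists on each of the 30 arrays (points; saline blue, dexamethasone orange), with the group mean ± SD in black. The astrocyte list averaged 13.5 in astrocytes under saline, 9.17 in neurons and 11.1 in tissue, and after dexamethasone it averaged 8.19 in neurons.

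Against tissue, astrocytes had higher Fgfr3 (4.36 ± 0.32), Slc7a10, an amino acid exchanger (3.64 ± 0.21), and the chemokine gene Ccl4 (4.00 ± 0.33). The chemokine genes Ccl3 and Cxcl1 were not detected in tissue and were at least 9.88-fold and at least 7.96-fold higher in astrocytes. Inflammatory genes were higher in astrocytes than in tissue for 18 of 20 and lower for 0, with the same counts when adjusted over the list alone (median 1.93, adjusted p = 1.82e-07, and 0.0248 with an estimated correlation). The astrocytes were sorted and the tissue was not, so sorting and cell type cannot be told apart here. The saline astrocyte samples also held microglia markers, at a list mean of 9.16 against 9.74 in saline tissue. Oligodendrocyte markers averaged 12.8 in the saline astrocyte samples, against 13.1 in saline tissue and 11.3 in saline neurons. The astrocyte samples were therefore not astrocytes alone, and changes called in astrocytes below are those of this preparation. Higher in tissue were the neuropeptide genes Tac1 (-4.53 ± 0.50, astrocytes minus tissue), Npy (-4.23 ± 0.24) and Pmch, the melanin-concentrating hormone precursor (-5.03 ± 0.76), and the long noncoding RNA Meg3 (-4.48 ± 0.21). Trh was detected on all 5 tissue arrays and on 0 astrocyte arrays. Endothelial markers were higher in astrocytes than in tissue for 12 of 14, 12 also when adjusted over the list alone (median 1.16, adjusted p = 4.98e-04, and adjusted p = 0.34 with an estimated correlation). The microglia list was lower for 7 of 16, with the same count when adjusted over the list alone (median -0.55, adjusted p = 0.0389, and adjusted p = 0.386 with an estimated correlation). That list call was lost without astrocyte saline replicate 1 (adjusted p = 0.0779) or 2 (0.0587), or tissue saline replicate 3 (0.0576) or 4 (0.0545). In all, 6860 genes differed in limma, 3207 higher and 3653 lower in astrocytes.

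Among the genes with the largest excess in neurons over tissue were Alas2, which makes haem in red cell precursors (5.38 ± 0.34), the haemoglobin gene Hbb-b2 (4.31 ± 0.28), Slc4a1, the anion exchanger of red cells (3.57 ± 0.23), and Top2a (3.71 ± 0.17) and Pbk (3.44 ± 0.27) of dividing cells. Pclaf, a replication factor, was not detected in tissue and was at least 7.87-fold higher in neurons. The list of blood markers was not called, with 3 of 7 higher and 1 lower, the same when adjusted over the list alone (median 0.32, adjusted p = 0.0556). Tissue had higher Ptgds (-5.46 ± 0.28, neurons minus tissue), the complement genes C1qc (-4.63 ± 0.22) and C1qb (-4.13 ± 0.19) of microglia, and Gfap of astrocytes (-3.93 ± 0.29). Medium spiny neuron markers were higher in neurons for 10 of 15, 13 when adjusted over the list alone, such as Gpr6 (1.34 ± 0.16), Penk (1.35 ± 0.36) and Foxp1 (1.19 ± 0.19). Their median was 0.94 (adjusted p = 1.14e-05, and adjusted p = 0.27 with an estimated correlation). Endothelial markers were higher for 10 of 14, 10 also when adjusted over the list alone, such as Flt1 (1.71 ± 0.28) and Pecam1 (1.39 ± 0.24). Their median was 0.92 (adjusted p = 1.74e-05, and adjusted p = 0.243 with an estimated correlation). Microglia markers were lower for 15 of 16, 15 also when adjusted over the list alone (median -3.18, adjusted p = 1.63e-19, and 0.00655 with an estimated correlation). Of the 21 astrocyte markers 19 were lower and 1 higher, with the same counts when adjusted over the list alone (median -2.12, adjusted p = 1.07e-14, and adjusted p = 0.157 with an estimated correlation). Of the 12 oligodendrocyte markers 10 were lower, 10 also when adjusted over the list alone (median -2.14, adjusted p = 1.75e-08, and adjusted p = 0.164 with an estimated correlation). In all, 3557 genes differed, 1463 higher and 2094 lower in neurons.

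In astrocytes, dexamethasone strongly raised known targets of the glucocorticoid receptor within 4 h. Fkbp5, a co-chaperone of the receptor, rose 14.4-fold, from 8.48 ± 0.49 to 12.3 ± 0.29 (log2 level, mean ± SD, n = 5 arrays each), a log2 change of 3.84 ± 0.23 (SE, limma adjusted p = 2.71e-05). Plin4, a lipid droplet protein, rose by 3.93 ± 0.61 from a level detected on 3 of 5 saline arrays (adjusted p = 0.00783), and Plin5 of the same family by 2.45 ± 0.28. The cell cycle inhibitor Cdkn1a rose by 3.44 ± 0.23, Mthfd2, an enzyme of mitochondrial folate metabolism, by 3.45 ± 0.19, and the kinase Map3k6 by 3.12 ± 0.24. Wnt7a, a secreted Wnt ligand, fell by 1.99 ± 0.16, and Il1b, the cytokine interleukin 1 beta, fell by 1.73 ± 0.27 and was detected on 2 of 5 arrays after dexamethasone. The astrocyte samples also held microglia markers (list mean 9.16 under saline), so the cells in which Il1b, or Nrros below, changed were not settled.

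Further large rises were those of Nrros (2.87 ± 0.28), a regulator of TGF beta activation, Tcim (2.79 ± 0.31), Insl6 (2.40 ± 0.28), the phospholipase Pla2g3 (2.39 ± 0.18) and the potassium channel subunit Kcng2 (2.30 ± 0.22). Klrg2 was not detected under saline and was at least 4.25-fold higher after dexamethasone. The further falls were 2810459M11Rik (-2.05 ± 0.30), Ddit4l (-1.47 ± 0.13), B230215L15Rik (-1.46 ± 0.31), Fam13c (-1.45 ± 0.18), Micall2 (-1.36 ± 0.21), the mitochondrial sodium and calcium exchanger Slc8b1 (-1.27 ± 0.15), Plekho2 (-1.25 ± 0.18), the kinesin Kif21b (-1.17 ± 0.25) and Prss35 (-1.14 ± 0.22). Snhg11, a noncoding RNA of neurons, also fell (-1.27 ± 0.26, adjusted p = 0.0329), with an adjusted p of 0.0813 when the chip was a block. Calls were lost on leaving out 1 array for Snhg11, Prss35, B230215L15Rik and Kif21b, and the other 20 of these 24 genes kept theirs in all 10 such fits.

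**Figure D2:**
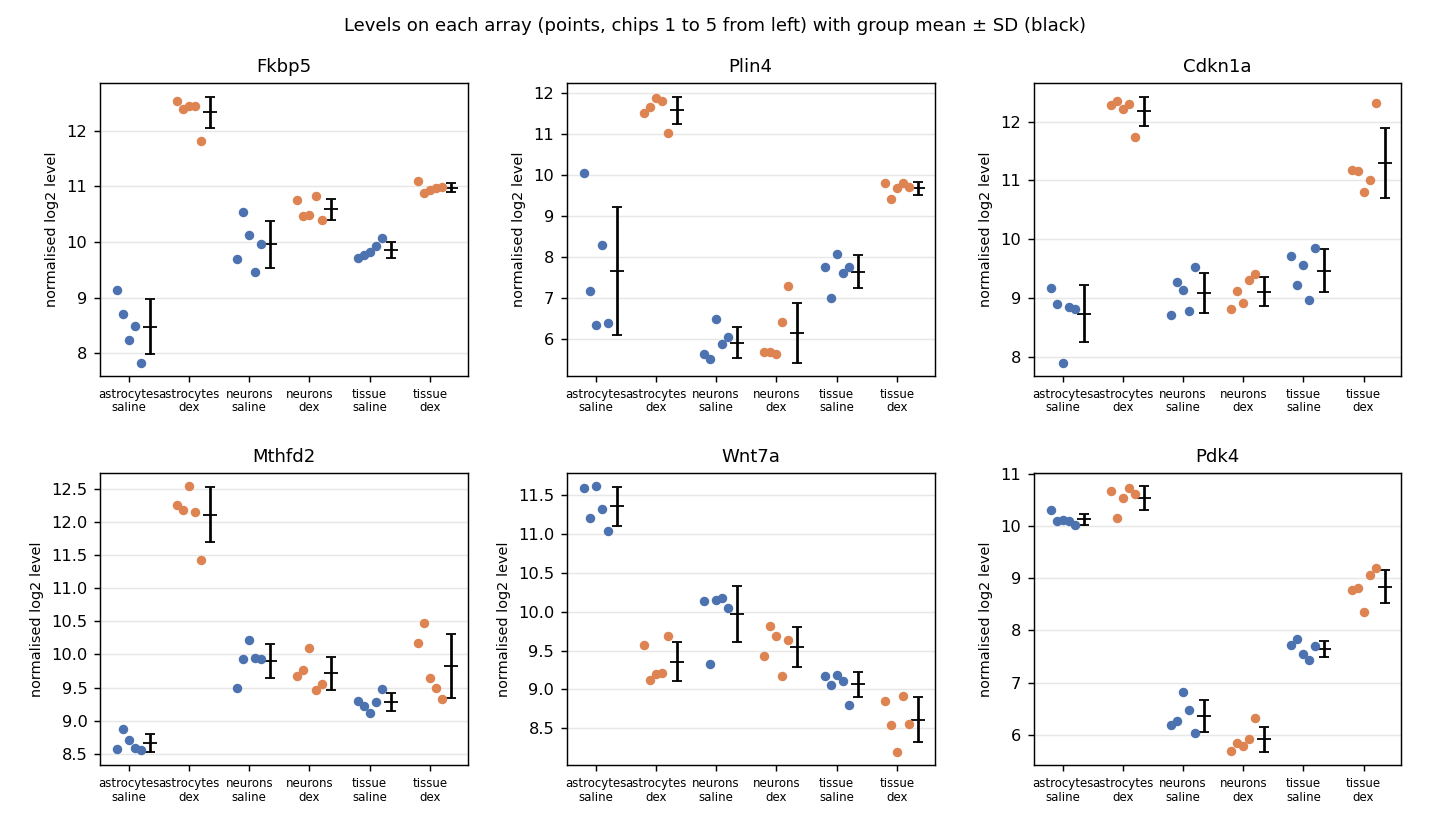
Normalised log2 levels of 6 genes on each array (points; saline blue, dexamethasone orange; n = 5 per group), with the group mean ± SD in black, by preparation. Fkbp5 averaged 12.3 in astrocytes after dexamethasone against 8.48 after saline, while Pdk4 changed by 0.41 ± 0.13 (log2, SE) there and by 1.19 ± 0.18 in tissue.

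Of the 40 measured genes of the glucocorticoid list, 19 rose in astrocytes, 0 fell and 21 were not called, and 31 rose when adjusted over the list alone. The list's median change was 0.83 (0.71 to 0.98 on the 5 chips; camera adjusted p = 9.21e-42, and 0.0115 with an estimated correlation). The kinase Sgk1, which regulates ion transport, rose by 2.01 ± 0.17, Arrdc2 by 1.74 ± 0.15, the transcription factor Zbtb16 by 1.42 ± 0.24 and Tsc22d3, an anti-inflammatory leucine zipper protein, by 1.05 ± 0.17. Several known targets were not called: Pdk4 changed by 0.41 ± 0.13 (adjusted p = 0.224), Per1 by 0.75 ± 0.32 (0.437) and Dusp1 by 0.26 ± 0.29 (0.955). Mt1 lay close to the highest intensity under both agents (16.05 and 16.04), where a rise cannot be seen.

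Of the list named growth restraint, 7 of 19 measured genes rose in astrocytes and 0 fell, with 10 rising when adjusted over the list alone (median 0.55, adjusted p = 2.66e-13, and adjusted p = 0.0548 with an estimated correlation). The list shares Cdkn1a, Ddit4 and Bcl6 with the glucocorticoid list, so the 2 results are not independent. Besides Cdkn1a, the rising genes included Trp53inp1 (1.59 ± 0.17), a target of p53, Irs2 (1.35 ± 0.20), an insulin receptor substrate, and Sesn1 (0.76 ± 0.10), an inhibitor of mTOR signalling. The list of inflammatory genes had a median of -0.23, and 1 of its 20 genes fell, Il1b, with 2 falling when adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.227 with an estimated correlation). Its call was lost without astrocyte saline replicate 1 (adjusted p = 0.0542) or 4 (0.134), or astrocyte dexamethasone replicate 5 (0.116). Ccl4 of that list changed by -0.59 ± 0.14 (adjusted p = 0.0585). In the same arrays the microglia markers had a median change of 0.10 (adjusted p = 0.637) and the astrocyte markers one of -0.02 (0.866). Neuron markers had a median of -0.16 and were lower on all 5 chips, with 1 of 16 falling, Snhg11, also when adjusted over the list alone (adjusted p = 0.0805). Choroid plexus markers were lower as a list on all 5 chips (median -0.56, -1.45 to -0.07), with 0 of 6 called either way, Ttr changing by -3.13 ± 1.23 (adjusted p of the list = 0.0338, and adjusted p = 0.179 with an estimated correlation). Without astrocyte saline replicate 1 its median was -0.25 (adjusted p = 0.0582). The list call was also lost without astrocyte saline replicate 3 (0.0701), or astrocyte dexamethasone replicate 1 (0.0553), 2 (0.0546) or 5 (0.0510). The interferon list had a median of -0.14 in astrocytes and was lower on 4 of 5 chips, with 0 of 18 called either way (adjusted p = 0.0433, and adjusted p = 0.999 with an estimated correlation). Its call was lost without astrocyte saline replicate 1 (0.0582), 2 (median -0.09, 0.167) or 5 (0.108), or astrocyte dexamethasone replicate 3 (-0.04, 0.461), 4 (-0.07, 0.305) or 5 (0.0967). The median was -0.37 without astrocyte dexamethasone replicate 1 and -0.25 without astrocyte saline replicate 3.

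In the clock list, Ciart, a repressor of the circadian clock, rose by 1.13 ± 0.21, the 1 called of 17 genes, with 1 up and 1 down when adjusted over the list alone and a list median of -0.03 (adjusted p = 0.999).

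In total limma called 233 genes in astrocytes, 186 up and 47 down, all with the same sign on the 5 chips. An unadjusted p under 0.05 was found for 1340 genes, where about 660 are expected by chance. At least a 2-fold change was seen for 122 of the rising and 19 of the falling genes. With the chip as a block 213 genes were called, and 166 of them were among the 233. Without astrocyte dexamethasone replicate 3, 131 genes were called, and without chip 5, a fit added after the data were seen, 150.

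**Figure D3:**
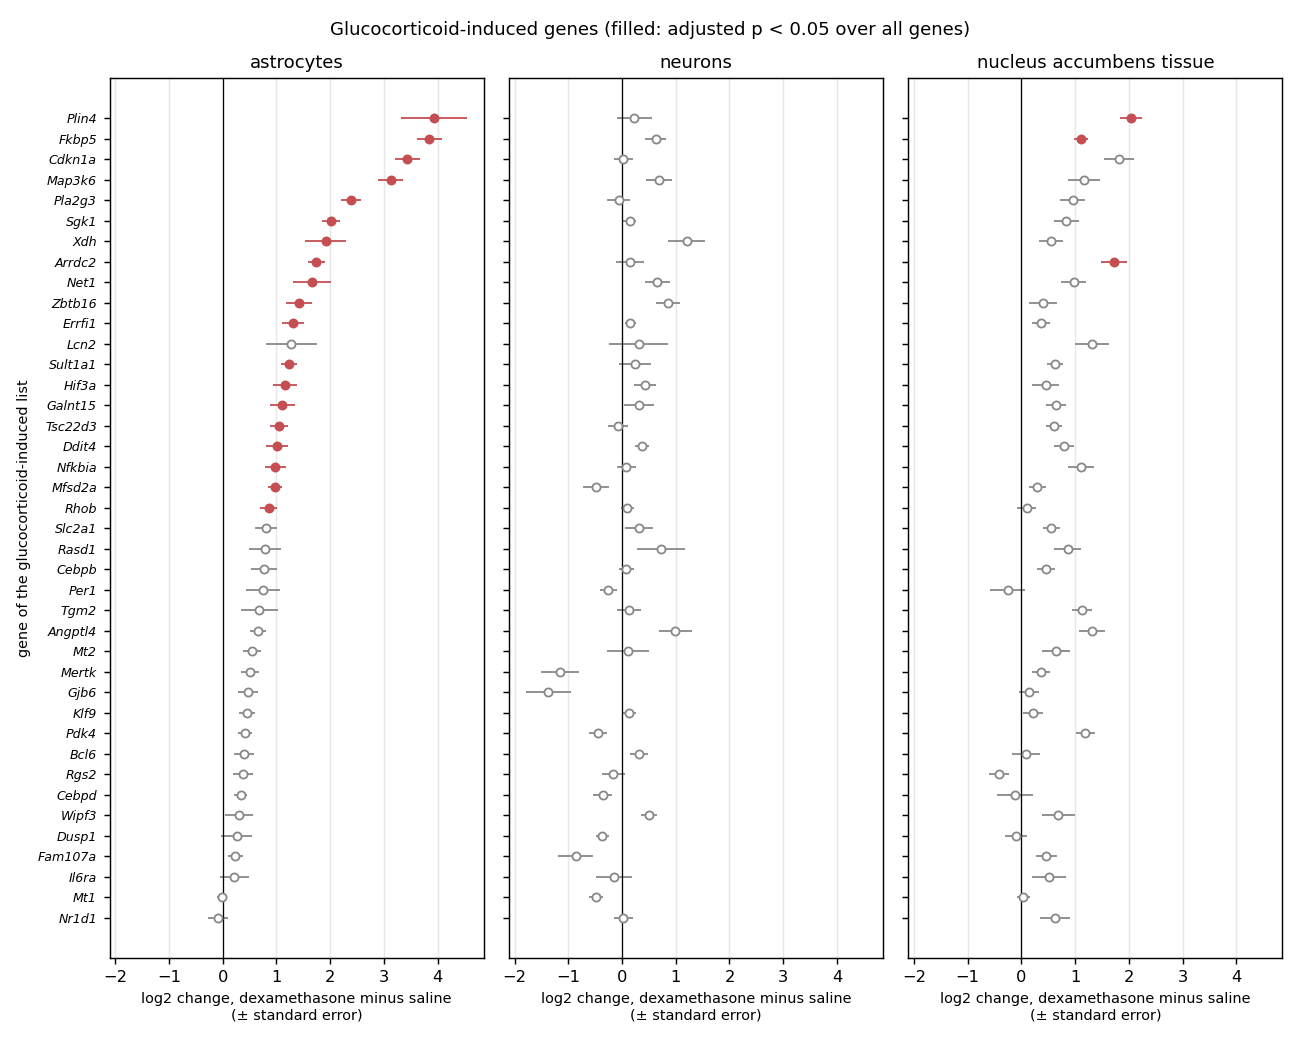
Log2 change after dexamethasone (± SE, n = 5 arrays per group) of the 40 measured genes of the glucocorticoid list in astrocytes, neurons and tissue, with genes at an adjusted p under 0.05 filled in red. In astrocytes 19 genes are filled, in tissue 3 and in neurons 0.

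In neurons, no gene was called after dexamethasone. Fkbp5 changed by 0.63 ± 0.19 (log2, SE, n = 5 arrays per group, limma adjusted p = 0.485), Zbtb16 by 0.85 ± 0.22 (0.447) and Xdh, the xanthine dehydrogenase gene, by 1.20 ± 0.35 (0.48). Cdkn1a changed by 0.03 ± 0.18 (0.996), and Plin4 was detected on 1 of the 10 neuron arrays. Insl6, named after its value was seen, changed by 1.87 ± 0.49 (0.447). The smallest p belonged to Sema6c, a semaphorin (-1.27 ± 0.18, adjusted p = 0.349), Myorg (-1.22 ± 0.20, 0.411), Pdlim4 (-1.41 ± 0.23, 0.411), the receptor phosphatase Ptprz1 (-1.08 ± 0.19, 0.432) and Trim47 (0.432), each lower on all 5 chips. Trim47 was detected on all 5 saline arrays and on 0 after dexamethasone, so no size is given. The glucocorticoid list had 0 of 40 genes called, 5 up and 3 down when adjusted over the list alone, and a median of 0.13 (-0.21 to 0.31 on the chips, adjusted p = 0.0531). Its largest falls were Gjb6 (-1.37 ± 0.42), Mertk (-1.15 ± 0.35) and Fam107a (-0.87 ± 0.32). Under saline they averaged 14.8, 12.8 and 15.5 in astrocytes against 10.7, 8.19 and 11.2 in neurons. Gjb6 is also an astrocyte marker, so the list's median is not free of the shift of astrocyte markers given below. The list passed the threshold without neuron dexamethasone replicate 1 (adjusted p = 0.00777) or 3 (0.0234), and without neuron saline replicate 2 (0.0143), 3 (0.0156) or 5 (0.0404). Growth restraint genes had a median of 0.11, with 0 of 19 called either way (adjusted p = 0.0164, and adjusted p = 0.189 with an estimated correlation). Without neuron saline replicate 5 the median was 0.16, and the call was lost without neuron saline replicate 4 (median 0.05, adjusted p = 0.0539) or neuron dexamethasone replicate 5 (0.04, 0.0985).

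Astrocyte markers were lower in the neuron samples of dexamethasone-treated mice, by a median of -1.17 over 21 genes (camera adjusted p = 9.12e-18), although 0 were called one by one. Adjusted over the list alone, 14 were lower, and with an estimated correlation the adjusted p = 0.185. The chip medians ran from -2.00 to 0.004, lower on 4 of 5, and the list's mean level differed with an exact permutation p of 0.0159 (adjusted over the 25 lists, 0.0992). Cldn10 changed by -1.81 ± 0.36 (adjusted p = 0.432), the water channel gene Aqp4 by -1.36 ± 0.28 (0.432) and Slc7a10 by -1.93 ± 0.41 (0.432). Genes of glutamate, GABA and potassium handling had a median of -0.58, 0 called of 17 and 9 lower when adjusted over the list alone (adjusted p = 3.96e-10, and adjusted p = 0.185 with an estimated correlation). Slc6a11, a GABA transporter, changed by -1.43 ± 0.27. Oligodendrocyte markers had a median of -0.56, with 0 of 12 called either way (adjusted p = 9.43e-06, and adjusted p = 0.228 with an estimated correlation), and Mog changed by -0.93 ± 0.33. Without neuron saline replicate 4 their median was -0.37. Endothelial markers had a median of -0.40, 0 of 14 called and 2 lower when adjusted over the list alone (adjusted p = 1.85e-05, and adjusted p = 0.27 with an estimated correlation). Their median was -0.20 without neuron dexamethasone replicate 3 and -0.25 without neuron saline replicate 5.

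Beside these shifts of other cell types, the inflammatory list in neurons had a median of -0.32, with 0 of 20 genes called either way (adjusted p = 6.9e-04, and adjusted p = 0.185 with an estimated correlation). Without neuron dexamethasone replicate 1 it was -0.20. The interferon list also had a median of -0.32, 0 of 18 called and 1 lower when adjusted over the list alone (adjusted p = 1.75e-04, and adjusted p = 0.208 with an estimated correlation), Gbp2 changing by -0.98 ± 0.20. Markers of neurons had a median of 0.08 (adjusted p = 0.2) and those of medium spiny neurons one of 0.01 (0.67). With limma 0 of 13209 genes were called and 927 had an unadjusted p under 0.05, where about 660 are expected by chance. Leaving out neuron saline replicate 2 gave 31 calls, 20 up and 11 down, and fitting all 30 arrays together gave 51, 6 up and 45 down.

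In tissue, 5 genes rose and 0 fell, and all 5 also rose in astrocytes. Plin4 rose by 2.04 ± 0.20 (log2, SE, n = 5 arrays per group, limma adjusted p = 0.00382), Arrdc2 by 1.73 ± 0.24 (0.0354), Ms4a6d, a membrane protein of macrophages, by 1.71 ± 0.22 (0.0212), Insl6 by 1.48 ± 0.20 (0.0331) and Fkbp5 by 1.11 ± 0.14 (0.0210). With the chip as a block, 2 genes were called, Plin4 and Arrdc2, and the adjusted p was 0.131 for Ms4a6d, 0.241 for Insl6 and 0.208 for Fkbp5.

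Short of the threshold in tissue were Cdkn1a (1.82 ± 0.28, adjusted p = 0.0533), Pdk4, which restrains glucose oxidation (1.19 ± 0.18, 0.0533), and Tgm2, a transglutaminase (1.13 ± 0.19, 0.0895). As a group, the 40 genes of the glucocorticoid list rose in tissue (median 0.61, 0.60 to 0.65 on the 5 chips, adjusted p = 7.64e-34, and 2.34e-04 with an estimated correlation), 3 of them called and 20 rising when adjusted over the list alone. Growth restraint genes rose too (median 0.35, adjusted p = 1.61e-09, and 0.0118 with an estimated correlation), with 0 of 19 called and 4 rising when adjusted over the list alone. Among them Trp53inp1 changed by 1.07 ± 0.24 (adjusted p = 0.303), Ddit4, an inhibitor of mTOR signalling, by 0.80 ± 0.18 (0.33) and Txnip, an inhibitor of glucose uptake, by 0.77 ± 0.18 (0.382). The glycolysis and lactate list had a median of 0.12, 0 of 24 called and 2 higher when adjusted over the list alone, Pdk4 and the glucose transporter Slc2a1 (0.56 ± 0.16). Its adjusted p was 0.0181, with adjusted p = 0.597 with an estimated correlation, 0.0592 without tissue saline replicate 1, 0.0611 without tissue saline replicate 5 and 0.242, with a median of 0.03, without tissue dexamethasone replicate 5. Microglia markers had a median of -0.13 (adjusted p = 0.349), 0 of 16 called and 2 lower when adjusted over the list alone, such as Cx3cr1 (-1.08 ± 0.23, adjusted p = 0.277).

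In tissue 753 genes had an unadjusted p under 0.05, where about 660 are expected by chance. Tissue dexamethasone replicate 5 lay farther from its group mean than the other arrays of its group did, and without it 14 genes were called, 10 up and 4 down. Without tissue saline replicate 5 there were 5 calls, and without any one of the other 8 arrays 1 or 2. Without chip 5, a fit added after the data were seen, there were 11. On leaving out 1 array, Plin4 kept its call in all 10 fits, Ms4a6d in 4, and Arrdc2, Insl6 and Fkbp5 in 2 each.

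The difference between the responses was tested directly. Against neurons, astrocytes responded more strongly for Mthfd2 (difference of log2 changes 3.64 ± 0.28 SE, limma adjusted p = 2.06e-09), Nrros (3.61 ± 0.35), Cdkn1a (3.41 ± 0.35) and Fkbp5 (3.22 ± 0.27, adjusted p = 1.53e-08), with 5 arrays in each of the 4 groups. Kcng2 (2.61 ± 0.43) and Pla2g3 (2.45 ± 0.30) followed. The microglia list averaged 9.16 in astrocytes and 6.74 in neurons under saline, so a difference such as that of Nrros need not lie in astrocytes. Plin4, Klrg2, Tcim and Plin5 were called too, but Plin4 was detected on 1 neuron array and the others on 0, so the sizes of their differences are not given. Gsdmc2, a gasdermin, differed in the other direction (-2.27 ± 0.39), changing by -1.01 ± 0.29 in astrocytes and 1.26 ± 0.30 in neurons and called in neither. Lower too were Wnt7a (-1.57 ± 0.24) and Trib2, a pseudokinase (-1.39 ± 0.19). Il1b was called in that direction but detected on 0 neuron arrays. The response differed for 109 genes, 98 up and 11 down, and 81 of them were also called in astrocytes and 0 in neurons. The changes had opposite signs in astrocytes and neurons for 79 and were larger in astrocytes for 88. Selection for a large difference itself favours opposite signs, and some neuron changes lay near 0, such as that of Pla2g3 (-0.06 ± 0.21). With 0 called in neurons, the signs do not show opposite responses. Without tissue dexamethasone replicate 5, which enters through the shared spread, 165 genes were called.

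By list, the glucocorticoid genes differed by a median of 0.77 between astrocytes and neurons, 12 of 40 up and 0 down, 22 up when adjusted over the list alone (adjusted p = 8.75e-36, and 1.19e-04 with an estimated correlation). That list includes the astrocyte marker Gjb6, so the shift of astrocyte markers in the neuron samples enters this difference. Growth restraint genes differed by 0.40, 2 of 19 up and 6 up when adjusted over the list alone (adjusted p = 9.93e-08, and 0.0165 with an estimated correlation). Astrocyte markers differed by 1.04, 6 of 21 up and 12 up when adjusted over the list alone (adjusted p = 2.82e-16, and 0.0209 with an estimated correlation); the examples were Cldn10 (1.81 ± 0.36) and Aldoc, an aldolase (1.54 ± 0.34). The same list had medians of -0.02 in astrocytes and -1.17 in neurons. Neuron markers differed by -0.25, 1 of 16 down, also when adjusted over the list alone (adjusted p = 0.00295, and adjusted p = 0.274 with an estimated correlation), a call lost without astrocyte dexamethasone replicate 4 (median -0.08, adjusted p = 0.0784). Without astrocyte saline replicate 1 the median was -0.38. Choroid plexus markers differed by -0.73, 0 of 6 called either way (adjusted p = 0.0296, and adjusted p = 0.449 with an estimated correlation). That call was lost without astrocyte saline replicate 1 (0.0788) or 3 (0.0676), astrocyte dexamethasone replicate 2 (0.0525), neuron saline replicate 1 (0.0891), or neuron dexamethasone replicate 2 (0.0624) or 3 (0.0617). Glutamate, GABA and potassium handling genes differed by 0.48, 2 of 17 up and 6 up when adjusted over the list alone (adjusted p = 6.31e-06, and adjusted p = 0.0988 with an estimated correlation).

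Between astrocytes and tissue the response differed for 47 genes, 42 up and 5 down, of which 42 were also called in astrocytes and 1 in tissue. The differences in favour of astrocytes were led by Mthfd2 (2.91 ± 0.28, adjusted p = 3.98e-07) and Fkbp5 (2.73 ± 0.27, adjusted p = 6.26e-07), followed by C130040D06Rik (2.39 ± 0.49), Dleu7 (2.14 ± 0.44), Nrros (2.14 ± 0.35) and Map3k6 (1.96 ± 0.39). Klrg2 and Tcim were called too, each with a saline group in which it was not detected. Of the 30 fits that left out 1 array, C130040D06Rik was called in 25 and Dleu7 in 26. Lower in astrocytes were the changes of Gsdmc2 (-1.85 ± 0.39), Wnt7a (-1.54 ± 0.24), Snhg11 (-1.30 ± 0.28) and Cbr3, a carbonyl reductase (-1.08 ± 0.25). Of those 30 fits, Gsdmc2 was called in 21, Snhg11 in 18 and Cbr3 in 8. Il1b, named after its value was seen, was the remaining call, lower on 4 of 5 chips and detected on 0 tissue arrays. The glucocorticoid list differed by a median of 0.34, 5 of 40 up and 0 down, 12 up and 1 down when adjusted over the list alone (adjusted p = 7.81e-07, and adjusted p = 0.443 with an estimated correlation). Choroid plexus markers differed by -0.91, 0 of 6 called either way (adjusted p = 0.00282, and adjusted p = 0.443 with an estimated correlation), a call lost without tissue dexamethasone replicate 1 (median -0.53, adjusted p = 0.0560). Neuron markers differed by -0.20, 1 of 16 down, also when adjusted over the list alone (adjusted p = 0.00596, and adjusted p = 0.443 with an estimated correlation), a call lost without astrocyte dexamethasone replicate 4 (median -0.04, adjusted p = 0.0980) or astrocyte saline replicate 5 (-0.09, 0.0654). Without astrocyte saline replicate 1 or 3 the median was -0.32 or -0.30. Scaling to the 75th percentile gave 33 up and 12 down, 73.3% up against 89.4%, and moved the median of all genes in this comparison from 0.04 to -0.06. Fewer genes were called without astrocyte dexamethasone replicate 2 or 3 (20 each), 4 (22) or 1 (25), without tissue saline replicate 1 or 3 (21 each) or 5 (24), and without tissue dexamethasone replicate 2 (30).

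Between neurons and tissue 7 genes differed, all with lower changes in neurons, and 1 of them was called in tissue and 0 in neurons. Pdk4 (adjusted p = 7.72e-04) and Ms4a6d (0.0471) were called, but Pdk4 was detected on 1 of the 10 neuron arrays and Ms4a6d on 0, so no sizes are given. Cdkn1a differed by -1.80 ± 0.35 (0.0471). Slc7a10 (-2.00 ± 0.39, adjusted p = 0.0471), Aldoc (-1.75 ± 0.34, 0.0471), Fads2, a fatty acid desaturase (-1.76 ± 0.33, 0.0471), and Fam20a (-1.38 ± 0.27, 0.0477) had adjusted p of 0.103, 0.0688, 0.0609 and 0.0657 with the chip as a block, which called 5 genes, 3 of them among the 7. Slc7a10 and Aldoc are astrocyte markers. Under saline Slc7a10, Fads2 and Fam20a averaged 8.60, 7.66 and 8.24 in neurons against 13.9, 11.4 and 13.3 in astrocytes. The differences of these genes cannot be told apart from the shift of astrocyte markers in the neuron samples, whose source stays open. The glucocorticoid list differed by a median of -0.45, 2 of 40 down and 14 down when adjusted over the list alone (adjusted p = 7.8e-18, and 0.00531 with an estimated correlation). That list includes the astrocyte marker Gjb6, so the shift enters this difference too. Astrocyte markers differed by -1.11, 2 of 21 down and 13 down when adjusted over the list alone (adjusted p = 3.62e-25, and 0.00531 with an estimated correlation). On leaving out 1 array, Pdk4 was called in all 30 fits, Cdkn1a in 7, Fads2 in 6, Ms4a6d in 5, Slc7a10 in 4 and Fam20a in 3. The count of genes was 27 without neuron saline replicate 2, 15 without neuron dexamethasone replicate 2, 10 without neuron saline replicate 4, 7 without neuron dexamethasone replicate 4 and 1 to 4 without any other array.

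Genes called in astrocytes tended to move the same way in tissue, most by smaller amounts, which their selection in astrocytes itself favours. Of the rising genes, 3 changed at least as much in tissue: Ms4a6d (1.71 ± 0.22 there, 1.21 ± 0.25 in astrocytes), and Nfkbia (1.11 ± 0.25, adjusted p = 0.303) and Depp1 (1.68 ± 0.26, 0.0533), which were not called in tissue and were named after their values were seen. The 186 rising genes had a median change of 1.13 in astrocytes and 0.25 in tissue, where 143 were positive, 76.9% against 43.2% of all genes (camera p = 5.17e-24, and p = 3.07e-05 with an estimated correlation). The 47 falling genes had a median of -0.41 in tissue, where 41 were negative, 87.2% against 56.8% of all genes (p = 6.84e-04 with an estimated correlation). In neurons the rising genes had a median of 0.02, with 98 of 186 positive (camera p = 0.0674), and the falling genes one of -0.13, with 33 of 47 negative (p = 0.00888, and p = 0.107 with an estimated correlation). The 5 genes called in tissue were all among those called in astrocytes, against 0.0704 expected for independent lists (Fisher's exact test, p = 1.64e-09). Across the 13209 genes, which are not independent replicates, the log2 changes of astrocytes and tissue correlated with r = 0.211 (rho = 0.137), those of astrocytes and neurons with r = 0.0981 (rho = 0.0738), and those of neurons and tissue with r = 0.135 (rho = 0.123). The last r was 0.0353 without chip 5 and 0.0684 without neuron saline replicate 4. Each preparation had its own saline arrays, so no control array was shared between the comparisons.

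**Figure D4:**
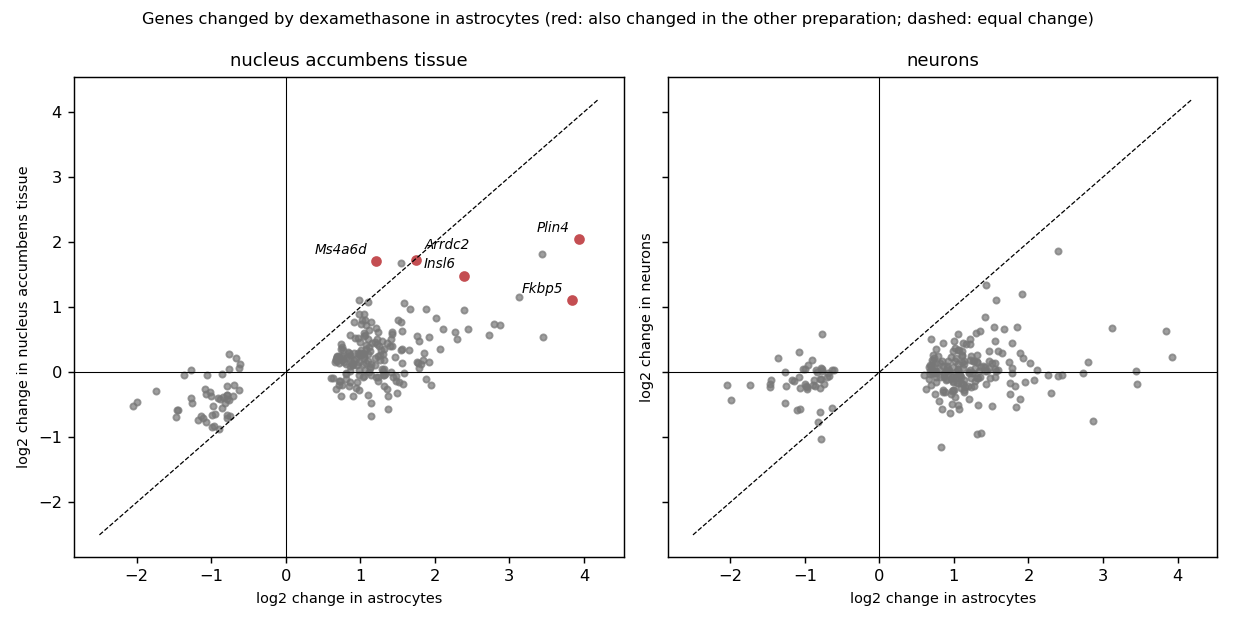
Log2 change of the 233 genes called in astrocytes (horizontal axis) against their log2 change in tissue and in neurons (vertical axes), 1 point per gene, with genes also called there in red and equal change dashed. In tissue 143 of the 186 rising genes lie above 0 and 5 are called, and in neurons 98 lie above 0 and 0 are called.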

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

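For the astrocyte markers in the neuron samples, the comparison with the endothelial list and the change within astrocytes were tests chosen after the result was seen, as were the comparisons with the other marker lists and those of single tissue genes with their predicted change.

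Astrocyte markers had a median change of -1.17 in the neuron samples of dexamethasone-treated mice. Lower expression within astrocytes is argued against, since the list changed by -0.0193 ± 0.187 (SD, n = 5 chips) in the astrocyte samples. A lower share of every non-neuronal cell type alike stays open: of the lists mostly detected in neurons, the astrocyte list differed by more than the spread from the endothelial (-0.69 ± 0.48) and oligodendrocyte precursor lists (-0.87 ± 0.71) but not from the oligodendrocyte list (-0.55 ± 0.71), and the mural (-0.74 ± 0.60), microglia (-0.94 ± 0.69) and choroid plexus (-1.26 ± 1.06) lists were mostly near background. Less astrocyte RNA carried over could also account for the pattern, and 145 further genes much higher in astrocytes than in neurons had a median change of -0.42 ± 0.36, with 133 lower, between the -0.5 this asked for and the -0.2 that would have counted against it. These 2 explanations and a change in the neurons themselves cannot be told apart, because the 145 genes fall between the bounds and the marker lists separate only in part.

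Some genes of red cells (Alas2, Hbb-b2, Slc4a1) and of dividing cells (Top2a, Pbk) were far higher in the neuron samples than in tissue under saline, while the fixed list of blood markers was not called (median 0.32, camera adjusted p = 0.0556). Whole blood was tested on 11 genes of white blood cells, with a median of 0.0919 ± 0.135 (SD, n = 5 chips), which does not decide, because only 1 of the 11 was detected on all 5 neuron arrays and 3 on all 5 tissue arrays. For red cell precursors, 15 further genes had a median of 0.40 ± 0.23 with 7 higher and 0 lower, among them Epor (1.40), short of the 0.5 asked for, so their presence stays open. For newborn neurons, 22 genes had a median of 1.23 ± 0.15, with 17 higher, among them Ccnd2 (2.55), Dlx2 (2.37) and Dcx (1.39). That passed the 0.5 asked for. The general neuron list averaged 12.12 ± 0.08 in neurons and 12.14 ± 0.09 in tissue (SD, n = 5 saline arrays each), which argues against enrichment of all neurons as the source. Medium spiny neuron markers did pass 0.5, with a median of 0.94, so an excess of that neuron type cannot be told apart here. Whether newborn neurons contribute the genes of dividing cells stays open.

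Most genes called in astrocytes changed less in tissue, which their selection in astrocytes itself favours, and the difference was called for 47 of 13209 genes. Dilution of the astrocyte response by RNA of other cells could account for much of it: with 17.7% of tissue RNA assigned to astrocytes, the median observed change of the 186 rising genes was 0.25 and the predicted one 0.32, a difference of -0.0796 ± 0.0932 (SD, n = 5 chips; rho = 0.376 across these genes, which are not independent replicates). A response of other tissue cells stays open: 4 glucocorticoid genes with at most 8.08% of their tissue transcript assigned to astrocytes had a median tissue change of 0.76 ± 0.27 and exceeded the change predicted from dilution by 0.35 ± 0.26. They went both ways, with Fkbp5 at 1.11 (0.93 predicted), Sgk1 at 0.83 (0.32), Wipf3 at 0.69 (0.01) and Rgs2 at -0.42 (0.01). Of the genes called in tissue, Plin4 changed by 2.04 with 1.83 predicted, but Arrdc2 by 1.73 with 0.61, Ms4a6d by 1.71 with 0.34 and Insl6 (1.87 in neurons, not called) by 1.48 with 0.35, so dilution alone leaves an excess in those 3, which were picked for their large tissue change. The predictions took the astrocyte samples as astrocytes alone, although those samples also held oligodendrocyte and microglia markers.

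The response differed between preparations, by interaction tests, for 109 genes between astrocytes and neurons, 47 between astrocytes and tissue and 7 between neurons and tissue. Among probes without a gene name, which no comparison above used, 29 of 3163 were called in astrocytes, 19 up.

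Single arrays far from the other 4 of their group were found in 11 of 154 groups tested, where chance alone gives about 1 in 20, or 7.7. Tissue dexamethasone replicate 5 lay 0.703 from its group mean (others 0.373 to 0.438) and tissue saline replicate 2 lay 0.352 from its own (others 0.264 to 0.281). The blood list was at 9.785 on astrocyte dexamethasone replicate 1 (others 8.61 to 8.929) and at 9.765 on tissue dexamethasone replicate 4 (others 9.185 to 9.319). The microglia list was at 9.029 on astrocyte dexamethasone replicate 4 (others 9.24 to 9.296). In neurons, the oligodendrocyte precursor list was at 9.559 on dexamethasone replicate 4 (others 8.869 to 9.019) and the mural list at 5.968 on dexamethasone replicate 3 (others 6.279 to 6.367). Astrocyte dexamethasone replicate 5 had Fkbp5 at 11.82 (others 12.39 to 12.53) and Cdkn1a at 11.74 (others 12.21 to 12.35). Cdkn1a was at 7.911 on astrocyte saline replicate 3 (others 8.829 to 9.183), and Plin4 at 9.417 on tissue dexamethasone replicate 2 (others 9.689 to 9.799).

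Chance as the source of the counts was tested on 100 drawn splits of the arrays into groups of the same sizes, the real split included. The splits argued against it for astrocytes (1 split with as many genes, the real 233 against at most 4 in the others) and for tissue (1 split, 5 against 1). Most of them broke the pairing by chip. In each preparation 13 drawn splits parted the arrays of every pair, and only the real one gave as many genes. These are too few to exclude chance with the pairing kept. In neurons the real count was 0, which all 100 splits reach by construction (the highest gave 11), so the splits say nothing there. For response differences the splits used differences within chips. They argued against chance between astrocytes and neurons (1 split, 116 against 1) and between astrocytes and tissue (1 split, 16 against 0). Between neurons and tissue this fit called 0 for the real split, which all 100 reach by construction (the highest gave 1), so it tests nothing about the 7 genes called on all 30 arrays. For the preparations 1 split each reached the real 7691, 6860 and 3557, against highest others of 6, 177 and 11, which argues against chance.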

How the results depend on the processing

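The fits without chip 5, the background model without control probes and the astrocyte marker covariate were chosen after the result was seen.

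With the chip as a block, tissue had 2 calls and astrocytes 213, against 5 and 233. Only 166 of the 233 astrocyte calls were among the 213. Apart from the genes, lists and counts given beside their results, the block brought 3 lists past the threshold, immediate early genes (adjusted p = 0.0283) and oligodendrocyte precursor markers (0.0252) in neurons and choroid plexus markers in tissue (0.0338), and changed no other call of the genes and lists named. No list shift or named gene past the threshold reversed its direction; the glucocorticoid list between neurons and tissue under saline, not called, went from -0.11 to 0.04 with 75th percentile scaling.

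Astrocytes had 369 calls with all 30 arrays in one fit, 373 with a trended and robust variance, 150 without chip 5 and 380 at an adjusted p under 0.1. Neurons had 51 with all 30 arrays and 0 with the marker covariate, where 518 genes had an unadjusted p under 0.05 against about 660 expected by chance. Tissue had 8 calls without background correction, from the deposited value table and with the strict filter, 12 with all 30 arrays, 24 with array weights, 11 without chip 5 and 10 at an adjusted p under 0.1. The glucocorticoid list in neurons passed the threshold without background correction (median 0.10, adjusted p = 0.0445), with the value table (0.0136, 0.0498) and with the mean of probes (0.12, 0.0352).

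The response difference between astrocytes and neurons had 251 calls with array weights and 171 at an adjusted p under 0.1, and that between astrocytes and tissue 75 without background correction. Between neurons and tissue there were 1 with no detection filter, 4 with the other background model, 2 with the strict filter, 37 with array weights, 13 with a trended and robust variance, 1 without chip 5 and 11 with every probe tested by itself. Testing every probe gave 12234 between astrocytes and neurons and 10822 between astrocytes and tissue under saline. With the strict filter the correlation across genes was 0.135 for astrocytes and neurons and 0.252 for neurons and tissue, and 0.0353 for the latter without chip 5. Testing every probe raises the number tested and the strict filter lowers it; for the other settings the cause was not tested.

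Leaving out 1 array at a time gave 131 to 226 calls in astrocytes, 0 to 31 in neurons and 1 to 14 in tissue. The response differences gave 83 to 165, 20 to 54 and 1 to 27, and the glucocorticoid list median in neurons ran from 0.0482 to 0.159. Of the list results under other settings 803 kept their side of the threshold, 140 lost it and 6 gained it, and of the named genes 1334 kept and 58 lost their call. Signal over background limits dim genes: 39.0% to 42.9% of probes were detected per group, and folds of genes near the background are compressed.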

Other observations

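The genes named in this part and the tests of the peptide genes were chosen after the values were seen.

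Genes of cholesterol and fatty acid synthesis were higher in astrocytes than in neurons under saline for 13 of 16 and lower for 1, with the same counts when adjusted over the list alone (median 1.40, adjusted p = 1.66e-04, and adjusted p = 0.0667 with an estimated correlation). Srebf1, a regulator of lipid synthesis, was higher by 3.42 ± 0.19 (SE, n = 5 arrays per preparation), and Msmo1 and Cyp51 of sterol synthesis by 2.38 ± 0.17 and 2.25 ± 0.16. Against tissue, 13 of 16 were higher in astrocytes and 2 lower, with the same counts when adjusted over the list alone (median 1.05, adjusted p = 6.1e-04, and adjusted p = 0.138 with an estimated correlation).

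Immediate early genes, which respond to neuronal activity, were higher in neurons than in tissue for 5 of 21 and lower for 0, with the same counts when adjusted over the list alone (median 0.43, adjusted p = 0.00952, and adjusted p = 0.377 with an estimated correlation). The median was 0.26 without tissue saline replicate 1 and 0.24 without neuron saline replicate 5. The 5 included Fos (1.66 ± 0.28), Npas4 (1.54 ± 0.30) and Fosb (1.49 ± 0.36). The neurons were sorted and the tissue was not, so sorting and cell type cannot be told apart here. Between astrocytes and neurons the list split, 10 higher and 7 lower in astrocytes, among them Egr4 (-3.32 ± 0.18) and Atf3, which was not detected in neurons and was at least 4.89-fold higher in astrocytes.

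In tissue, Pmch changed by -3.70 ± 1.01 after dexamethasone (7.89 ± 1.78 against 11.6 ± 2.08, mean ± SD, n = 5 arrays each) and was lower on all 5 chips, with a limma adjusted p of 0.502 and an exact permutation p of 0.0317. Hcrt changed by -2.51 ± 0.90 and was also lower on all 5 chips (adjusted p = 0.739, exact permutation p = 0.0714). Paired within chips the exact p was 0.0625 for each, the smallest that 5 pairs allow. Other peptide genes of the hypothalamus, Trh, Avp and Oxt, changed by -0.43 ± 0.31, -0.41 ± 0.36 and -0.16 ± 0.64.

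Of the sex-linked genes, Xist was at 5.84 and 5.53 on the saline and dexamethasone tissue arrays of chip 5, where Eif2s3y of the Y chromosome was at 11.01 and 8.79. The other 28 arrays had Xist between 9.25 and 11.4. The chip 5 neuron arrays had both, with Eif2s3y at 10.22 and 10.24 and Xist at 10.89 and 10.6, and neuron dexamethasone replicate 3 had Eif2s3y at 8.19. Of the other Y-linked genes, Uty (5.48 to 8.32) did not follow Eif2s3y over the 30 arrays and Kdm5d (5.13 to 8.14) followed it in part. Kdm5d was highest on neuron dexamethasone replicate 5 (8.14) and tissue saline replicate 5 (7.5). It was at 6.56 on neuron saline replicate 5 and 6.3 on tissue dexamethasone replicate 5. On tissue dexamethasone replicate 2 it was at 7.38, with Eif2s3y at 5.62. Whether each of these arrays held RNA of 1 mouse, as labelled, was not settled by these genes.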
